A study of Mus musculus with 8 samples.

How the data were processed

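Mouse embryonic stem cell lines HM-1 and R1 were compared on 8 cDNA microarrays with 2 colours. Both lines were hybridised together on each array, 4 arrays with untreated cells and 4 with cells given nocodazole, a drug that depolymerises microtubules and holds cells in mitosis. Per the labels, HM-1 carried Cy5 on untreated replicates 1 and 2 and on nocodazole replicates 1, 2 and 3, and Cy3 on the other three arrays. The labels therefore swap the dyes on 37.5% of the arrays, while the design text speaks of 50%. Total RNA was reverse transcribed and labelled indirectly, per the labels' protocols. The protocols also mention organs and a pooled reference from control animals, which the channel labels, HM-1 and R1 on every array, do not match. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

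The values are those of the deposited table, 1 log2 ratio per probe and array, and the scanner files were not used here. The authors' software, background correction and normalization are not given in the sources used here. The deposited log2 values hold 1 added offset per array. A ratio with a denominator of 0 stands in the table as a ratio of 100000, which is 16.6 on the log2 scale before the offset. These coded values numbered between 74 and 203 per array. They were set to missing, a choice made after the values were seen. Between 17928 and 19445 of 20355 probes had a value on an array, and the array medians as deposited lay between -0.19 and 0.12. No intensities were at hand, so the brightness behind a ratio is unknown. Between 11.0% and 19.5% of the values of an array equalled a ratio of whole numbers up to 10 (tolerance 0.0015 on the log2 scale), against 4.58% to 5.20% when the offset was shifted, so part of the spots were very dim. The number of arrays limits the precision.

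Gene symbols came from the platform's annotation. It listed 1 symbol for 14030 probes, several for 5 and none for 6320. Of the probes with a gene ID, 13994 matched the mouse RefSeq gene table (assembly GRCm38.p6), which was used for names alone. Probes with 1 and the same symbol were averaged per array, and a probe without a symbol stayed on its own. Of 16255 features, 14015 had a value on at least 3 arrays of each group and were tested, 8726 of them named.

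The direction of the ratios is not stated in the labels. A rule fixed beforehand correlated the untreated arrays of opposite dye over all features. A mean r above 0.1 meant ratios already turned to one direction, a mean r below -0.1 meant ratios of dyes, and anything between meant an unsettled direction. The mean r was -0.06 with the coded values kept and -0.12 with them left out, so the rule gives an unsettled direction in the first case and would turn the arrays with HM-1 in Cy3 in the second. The code for a denominator of 0 is positive on the 5 arrays labelled HM-1 in Cy5 and negative on the 3 labelled HM-1 in Cy3. The deposited signs were kept as the main reading, a choice that departs from the rule. The code's sign follows the dye label but does not show which way the ratios ran before. It therefore does not settle this choice, and the reading with the Cy3 arrays turned is given beside each comparison. HM-1 is known as an Hprt-deficient line, but no probe was named Hprt, so the rule for naming the numerator could not be used. By the same rule a nocodazole array with r below -0.3 to the mean of the others of its group leaves the fit. The lowest was -0.24, for replicate 4, and replicate 1 was at 0.04, so all arrays stayed in. Signs are those of the table, and no line is called higher. The log2 scale was read from the values, and the direction and the normalization stay unknown.

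Each array was centred on its median. The test was limma (version 3.58.1, with statmod 1.5.0 in R 4.3.3), with lmFit and eBayes over all 8 arrays, a coefficient for each group and a term for the dye label. Its p-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The comparisons were the ratio between the lines untreated, the same with nocodazole, the mean of both, and the difference between the conditions. Treated and untreated cells of 1 line never share an array, so the difference between conditions is a change of the ratio between the lines and gives no effect of nocodazole within a line.

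Of 31 gene lists, 29 had at least 5 members measured on all arrays and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The 2-cell-like genes and the Y-linked genes had 1 measured member each and were not tested. Camera was repeated with a correlation estimated per list, and fry was run beside it. The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. By that rule the line comparisons name genes past the threshold, of which there were none, and the change names the 5 genes of smallest p per direction. The text therefore also names 25 genes that were chosen after their values were seen. Only named genes with a value on all 8 arrays, clone names left out, were eligible. Of these, the 15 negative and 10 positive genes of smallest p in the fit of both conditions without nocodazole replicate 1 were taken. That array was doubted after the values were seen, because genes with 1 sign on the other 7 arrays had the opposite sign on it.

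The alternatives were no centring, scaling to 1 median absolute deviation, quantile normalization, no dye term, nocodazole replicate 3 given the opposite dye or turned, other filters on missing values, single probes, each group alone, robust and weighted variances, a replicate block, an estimated correlation, and leaving out each array in turn. Alternatives added after seeing the data were coded values kept, the Cy3 arrays turned, dim values left out, and nocodazole replicate 1 turned with the opposite dye. The fits were tested on simulated data with 14015 features. The changed features all had a value on every array, and the noise was independent, with 1 spread per feature over all arrays. On the real arrays the spread was not equal, with a standard deviation of 1.28 on nocodazole replicate 3. The simulated counts need not hold for the real data. With 100 features changed by 0.5 and 100 by 1 on the log2 scale and all arrays alike, the untreated comparison called 0 and 30 of them, and the comparison over both conditions called 12 and 63. With the changes reversed on nocodazole replicate 1, both comparisons called 0 at either size. With that array then left out the comparison over both conditions called 2 and 46, and the untreated comparison again called 0 at either size. No pair of arrays held the same hybridisation: the highest correlation between arrays was 0.22, and at most 0.148% of probes had the same value on a pair of arrays.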

Results

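The ratio between HM-1 and R1, a pair of mouse embryonic stem cell lines, was measured on 4 arrays from untreated cells and 4 arrays from cells given nocodazole. The title and design text state the aim as a comparison of the expression profiles of these lines with and without the drug. Arrays held between 17928 and 19445 values. The standard deviation of the log2 ratios was between 0.78 and 0.91 on 7 arrays and 1.28 on nocodazole replicate 3. Values below are log2 ratios with the sign of the deposited table, and which line stands in the numerator is not settled.

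By Pearson's r the arrays grouped by the dye that HM-1 was labelled with. This r over features, which are not independent replicates, lay between 0.02 and 0.22 for the 13 pairs of arrays with one dye label and between -0.23 and -0.01 for the 15 pairs with opposite labels. The ranges overlapped with Spearman's rho, at -0.0025 to 0.29 and -0.22 to 0.03. The component that followed the dye label held 1306 features at an unadjusted p under 0.05 and 0 past the threshold in limma, or 1 with array weights (adjusted p = 0.034). Genes of oxidative phosphorylation moved with the dye label (mean 0.09 on the log2 scale, camera adjusted p = 4.46e-05), and so did those of cytosolic ribosomal proteins (0.05, adjusted p = 0.000121). With an estimated correlation the adjusted p of these lists were 0.676 and 0.783.

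**Figure D1:**
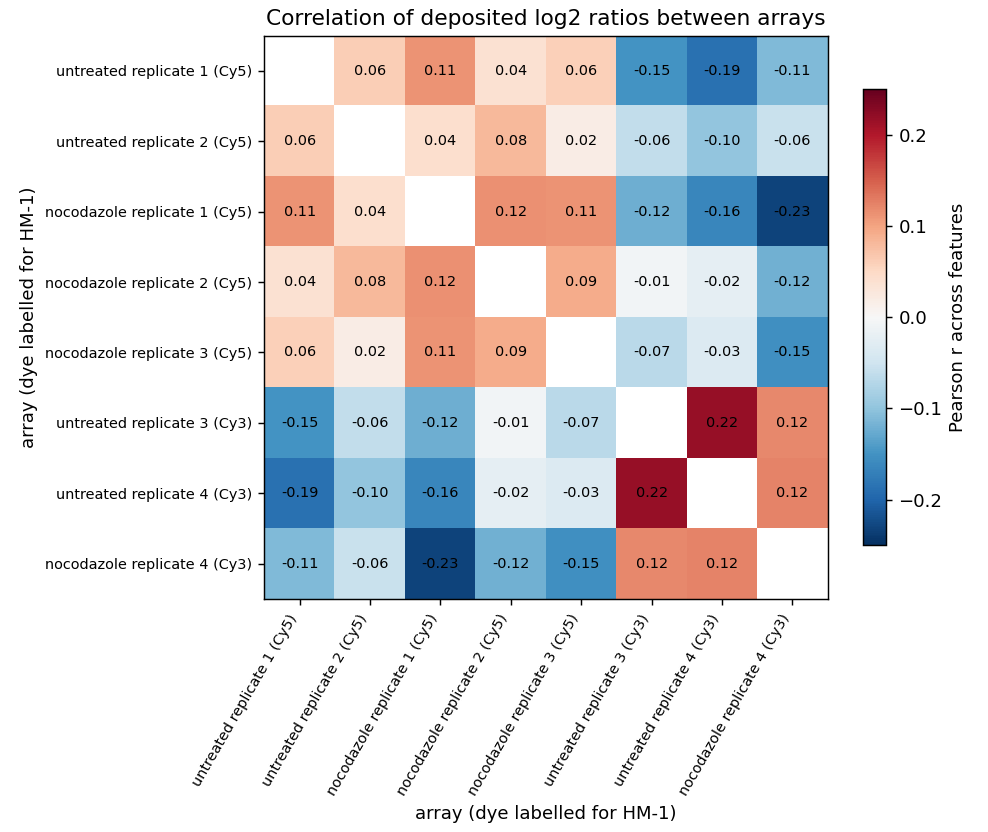
Pearson correlation over all features between each pair of the 8 arrays, ordered by the dye label of HM-1 (Cy5, then Cy3), with coded values left out. Pairs with one dye label lie between 0.02 and 0.22 and pairs with opposite labels between -0.23 and -0.01.

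In untreated cells, genes of primitive and definitive endoderm had negative ratios between the lines. The mean over the list was -0.37, 17 of its 22 measured members were negative, and 7 of these had an unadjusted p under 0.05. Dab2, an endocytic adaptor of the primitive endoderm, was at -1.04 ± 0.14 (SD, n = 4). Serpinh1, a collagen chaperone, was at -0.81 ± 0.29 (SD, n = 4), and Sparc, a matrix glycoprotein made in quantity by parietal endoderm, at -0.81 ± 0.15 (SD, n = 4). The lysosomal proteases Ctsl and Ctsh were at -0.74 ± 0.37 and -0.67 ± 0.11 (SD, n = 4), and the parathyroid hormone receptor Pth1r at -0.68 ± 0.10 (SD, n = 4). Other genes of the list did not share these values: Gata6, an early factor of primitive endoderm, was at 0.06 ± 0.39, Afp, a product of visceral endoderm, at -0.04 ± 0.21, and Col4a1, a basement membrane collagen, at 0.14 ± 0.07 (SD, n = 4 each).

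Lists of other cell types were negative as well without passing: feeder fibroblast markers at -0.14 (-0.17 to -0.11 on the 4 arrays, adjusted p = 0.129) and trophectoderm at -0.25 over 6 members (-0.47 to -0.08, adjusted p = 0.112). Genes of naive pluripotency had a mean ratio of 0.24, with 13 of 19 members positive. The medians over members on untreated replicates 1 to 4 were 0.24, 0.18, 0.11 and -0.10. On replicate 4, 10 of 19 members were negative although the mean was 0.39. Lefty1, an antagonist of Nodal signalling, was at 0.48 ± 0.21 and the transcription factor Klf2 at 0.68 ± 0.21 (SD, n = 4 each). Gdf3 was at 1.497 ± 2.58 (SD, n = 4), a spread larger than its mean, while Sox2 (0.17 ± 0.64) and Zfp42 (-0.03 ± 0.23) lay within the spread between arrays. The cholesterol biosynthesis list had a mean of -0.15 with 15 of 17 members negative. Among them were the sterol oxidase Msmo1 at -0.32 ± 0.28 and the fatty acid desaturases Scd1 at -0.41 ± 0.17 and Scd2 at -0.64 ± 0.72 (SD, n = 4 each). Other members did not share these values: Cyp51 was at 0.40 ± 0.91, Mvk at 0.0078 ± 0.29 and Sqle at -0.0065 ± 0.20 (SD, n = 4 each). On untreated replicate 1 the list mean was 0.03 with 7 of 17 members negative, and on replicates 2 to 4 it was between -0.23 and -0.17. Genes of the actin cytoskeleton and adhesion had a mean of -0.15 with 30 of 39 members negative. In this list the actin-severing protein Gsn was at -0.54 ± 0.27, the membrane-binding protein Anxa2 at -0.59 ± 0.19 and the epithelial keratin Krt8 at -0.98 ± 0.35 (SD, n = 4 each). Positive members included Actg1 at 0.19 ± 0.79, Cdh1 at 0.34 ± 0.65 and Rhoc at 0.48 ± 0.71 (SD, n = 4 each), with spreads larger than their means. The oxidative phosphorylation list was closer to 0, with a mean of -0.05, a median of -0.09 and 40 of 52 members negative. It split by dye label, at 0.07 and 0.06 on untreated replicates 1 and 2 and -0.20 and -0.12 on replicates 3 and 4, and lost its call in 10 of 20 alternatives (-0.08 to -0.03 with single arrays left out) and changed sign in 1.

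These 5 lists passed camera in limma, with adjusted p = 0.0033 for endoderm, 0.00909 for cholesterol biosynthesis and 0.0327 for pluripotency, actin and oxidative phosphorylation. None held with an estimated correlation (adjusted p = 0.678 with an estimated correlation for endoderm, cholesterol, pluripotency and oxidative phosphorylation, and 0.814 for actin), and fry gave an adjusted p of 0.303 for endoderm. No single feature passed the threshold in limma, over all 14015 features or for these 5 lists adjusted over the list alone. At an unadjusted p under 0.05 there were 888 features, 458 positive and 430 negative, where 701 are expected by chance, and the smallest adjusted p was 0.422. Of the 5, only endoderm kept its call without each untreated replicate in turn. Without replicate 2 or 3 it was the only one to do so, without replicate 1 cholesterol and oxidative phosphorylation did too, and without replicate 4 cholesterol and pluripotency. The actin list lost its call each time (adjusted p = 0.0509 to 0.136), with means between -0.17 and -0.13. With the Cy3 arrays turned, 0 features and 2 lists passed, oxidative phosphorylation at 0.11 and cytosolic ribosomal proteins at 0.08. The endoderm list was then at -0.0681 (adjusted p = 0.938), and 1484 features had an unadjusted p under 0.05.

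**Figure D2:**
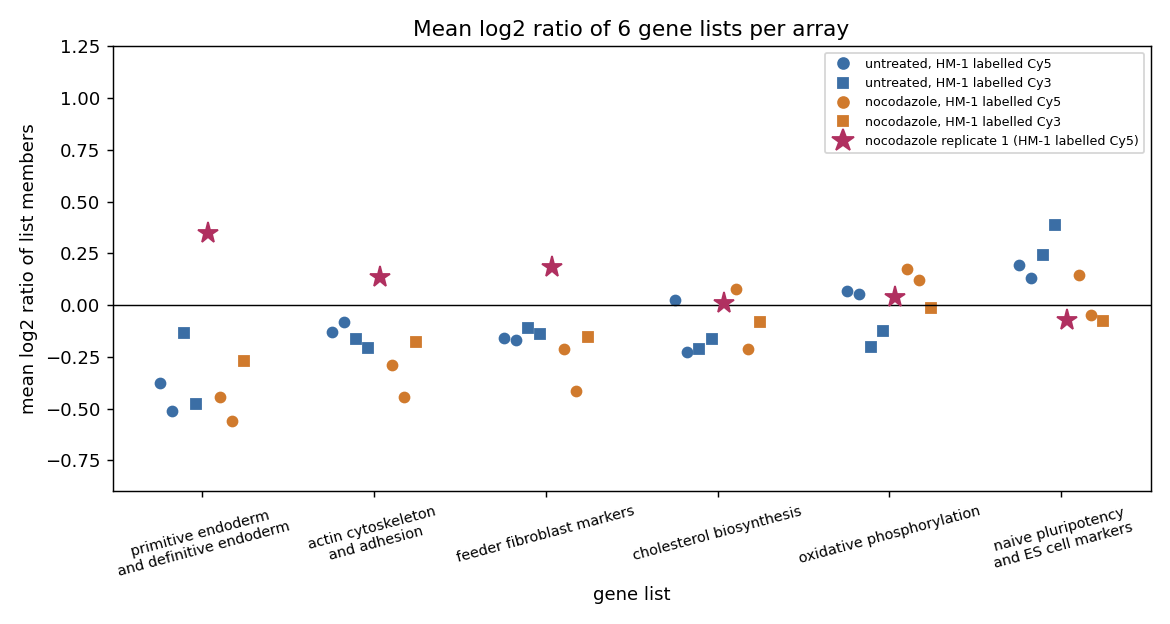
Mean log2 ratio of 6 gene lists on each of the 8 arrays, with the sign of the deposited table. The endoderm list lies between -0.56 and -0.13 on 7 arrays and at 0.35 on nocodazole replicate 1.

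With nocodazole, genes of the actin cytoskeleton and adhesion again had negative ratios. The mean was -0.20, with 35 of 39 members negative. Feeder fibroblast markers had a mean of -0.14, with 23 of 30 negative. Both lists had the opposite sign on nocodazole replicate 1: the actin list was at 0.14 there and between -0.44 and -0.18 on the other three arrays, and the fibroblast list was at 0.18 there and between -0.41 and -0.15 on the others. The spread within the group was therefore wide for single members, as for the calcium-binding protein S100a4 at -0.29 ± 0.66, the matrix glycoprotein Thbs1 at -0.32 ± 0.67 and Anxa2 at -0.35 ± 0.74 (SD, n = 4 each). The endoderm list had a mean of -0.22 (adjusted p = 0.101), with 0.35 on replicate 1 and -0.56 to -0.27 on the others.

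Camera in limma gave an adjusted p of 0.000159 for the actin list and 0.04999 for the fibroblast list, just under the threshold. Neither held with an estimated correlation (adjusted p = 0.863 with an estimated correlation for both). No feature passed in limma (smallest adjusted p 0.0638), and 0 members of these lists passed adjusted over the list alone. At an unadjusted p under 0.05 there were 405 features, 251 positive and 154 negative, where 701 are expected by chance. Without nocodazole replicate 4 there were 746, and without replicate 1 there were 681 with 0 features past the threshold. Without replicate 1, 3 lists passed, with the actin list at -0.26 over 41 members (adjusted p = 9.38e-08), the fibroblast list at -0.25 (adjusted p = 6.77e-06) and the endoderm list at -0.39 (adjusted p = 4.97e-06). None held there either (adjusted p = 0.225 with an estimated correlation for actin and fibroblast markers and 0.144 for endoderm). Replicate 1 was doubted for its opposite sign on such genes, so these calls without it are no independent support. Without nocodazole replicate 3 the actin list was at -0.11 (adjusted p = 0.0393) and the fibroblast list at -0.0486 (adjusted p = 0.583). Without nocodazole replicate 2 or 4 no list passed. The actin list was then at -0.17 (adjusted p = 0.0504) and -0.24 (adjusted p = 0.0601), and the fibroblast list at -0.12 (adjusted p = 0.357) and -0.13 (adjusted p = 0.561). With the Cy3 arrays turned 2 lists passed, oxidative phosphorylation at 0.09 and cytosolic ribosomal proteins at 0.01, with 0 features and the actin list at -0.0224 (adjusted p = 0.992).

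Lists tied to the action of the drug did not pass with nocodazole. Genes of G2 and mitosis had a mean of -0.04 with 29 of 44 members negative (camera adjusted p = 0.797). Tubulins, the subunits of the microtubules that nocodazole takes apart, had a mean of 0.11 over 11 members (adjusted p = 0.828). Apoptosis regulators were at 0.08 over 22 members (adjusted p = 0.797) and p53 targets at 0.0043 over 22 members (adjusted p = 0.871). Each array compares treated cells with treated cells, so these values bear on a difference between the lines and not on the response to the drug.

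Over both conditions, 254 of 7316 named genes measured on all arrays had a negative ratio on the 7 arrays other than nocodazole replicate 1, and 233 of these a positive one on that array. Positive on the 7 arrays were 83, of which 48 were negative on that array, a smaller share than among the negative genes. How many genes of one sign chance would give was not worked out. The 15 negative genes named here had the smallest p among the 7316 without nocodazole replicate 1. They were chosen after their values were seen, so their agreement on the 7 arrays is not an independent test. Prph, a neuronal intermediate filament, was at -0.95 ± 0.27 untreated (SD, n = 4), between -1.46 and -1.30 on nocodazole replicates 2 to 4, and at 1.54 on replicate 1. Cryab, a small heat shock protein, was at -1.04 ± 0.14 untreated (SD, n = 4), between -1.57 and -1.08 on those nocodazole arrays, and at 1.19 on replicate 1. Id1, an inhibitor of helix-loop-helix factors and a target of BMP signalling, was at -0.37 ± 0.08 untreated (SD, n = 4), between -1.35 and -1.15 on the same arrays, and at 1.32 on replicate 1.

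The others of the 15 were Sparc, Serpinh1, Dab2, Ctsl, Ctsh and Pth1r of the endoderm list, Krt8 and Anxa2 of the actin list, and Thbs1, with untreated means between -1.04 and -0.59, together with the heparan sulphate proteoglycan Gpc4 (-0.98 ± 0.18), the citrate transporter Slc13a5 (-0.64 ± 0.08) and the trypsin inhibitor Spink1 (-1.004 ± 0.33; SD, n = 4 each, untreated). Sparc is also a member of the fibroblast list and Krt8 of the trophectoderm list. On nocodazole replicate 1 these genes lay between 0.66 and 1.41. Of the 10 positive genes chosen in the same way, 5 were positive on all of the other 7 arrays. These were the ribosomal protein gene Rps15a (0.54 ± 0.18 untreated), Nsmce1 of the SMC5/6 complex (0.51 ± 0.23), the Hippo pathway adaptor Sav1 (0.92 ± 0.33), Lefty1 (0.48 ± 0.21) and the channel gene Pkd2l1 (0.29 ± 0.04; SD, n = 4 each). Lefty1 was at 0.06 on nocodazole replicate 1, and the others were negative there. The remaining positive genes, Ercc6, Dock1, Csnk1e, Pecam1 and Adamts17, were positive on 5 or 6 of the 7 arrays.

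**Figure D3:**
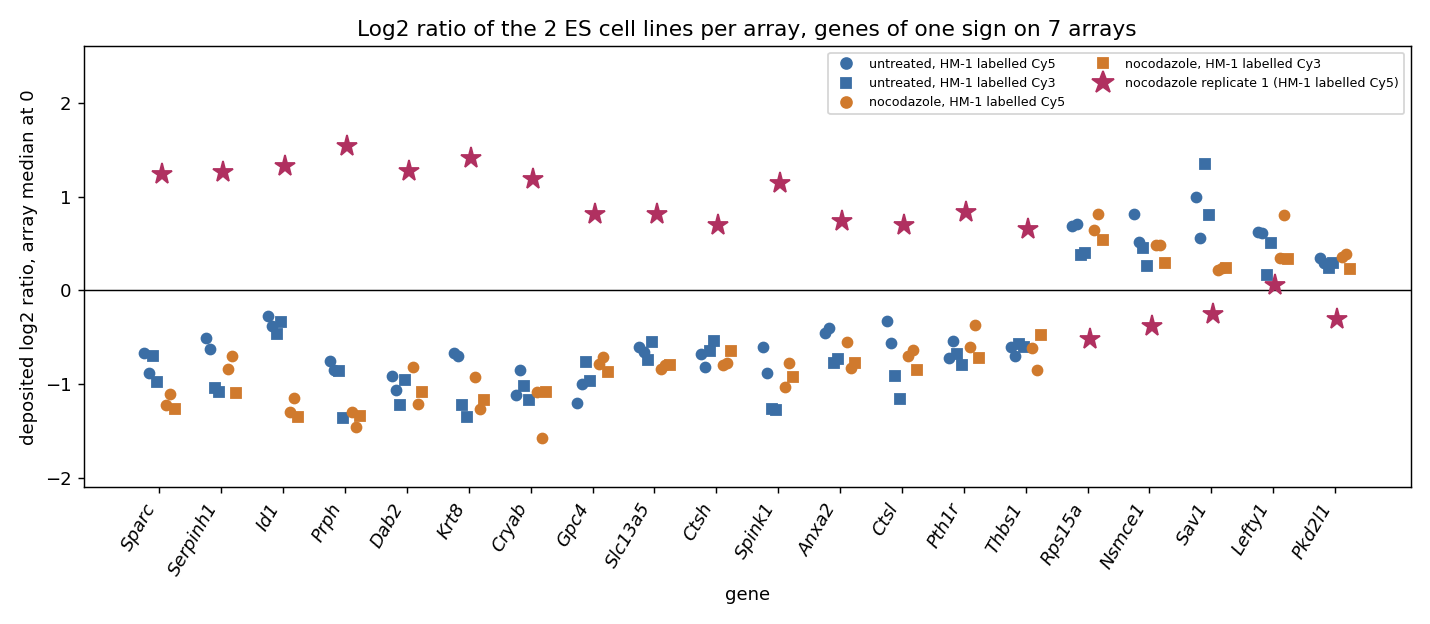
Log2 ratios of 20 genes on each of the 8 arrays, with the sign of the deposited table. The genes were chosen after their values were seen, without nocodazole replicate 1 (star). The 15 negative genes lie below 0 on 7 arrays and between 0.66 and 1.54 on that array.

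In the fit of all 8 arrays these 25 genes had an adjusted p of 0.897 in limma, and no feature passed over both conditions. At an unadjusted p under 0.05 there were 775 features, 426 positive and 349 negative. Without nocodazole replicate 1 the count was again 0, with 992 features at an unadjusted p under 0.05, 420 positive and 572 negative, and a smallest adjusted p of 0.0873, shared by Sparc (-1.01, SE 0.07), Serpinh1 (-0.88, SE 0.07), Id1, Prph and Dab2. With the Cy3 arrays turned no feature passed, and 22 of the 25 genes changed sign.

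The ratio between the lines differed between nocodazole and untreated cells for no feature that passed the test. The genes of smallest p are given as values. Prkag2, a regulatory subunit of the AMP-activated kinase, was at 0.90 ± 0.36 untreated (SD, n = 3) and -0.53 ± 0.20 with nocodazole (SD, n = 4), a fitted change of -1.61 (SE 0.18). Esrrb, a nuclear receptor of naive pluripotency, was at 0.06 ± 0.18 untreated (SD, n = 4) and at 2.03 ± 0.94 with nocodazole (SD, n = 3), a fitted change of 1.83 (SE 0.33). The AP-1 repressor Jdp2 went from 0.55 ± 0.23 to -0.88 ± 0.40 (SD, n = 4 each), and the cytokine gene Il24 had a fitted change of -1.50 (SE 0.16). Zcrb1 (-4.20) and Rpgrip1l (-0.93) completed the negative genes, and the fitted change of Zcrb1 was between -4.42 and -0.23 when single arrays were left out. The other positive changes were those of Pla2g12a (2.36), the repair gene Ercc8 (1.76), Cacul1 (1.495) and Nme2 (1.24). The fitted changes include the dye term and can differ from the difference of the group means. For Nme2 these means were alike, 0.20 ± 1.61 untreated (SD, n = 3) and 0.22 ± 1.53 with nocodazole (SD, n = 4), and for Zcrb1 they were 0.80 ± 2.31 and -0.75 ± 0.41 (SD, n = 3 each).

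These 10 genes had adjusted p between 0.878 and 0.996 in limma. No feature passed (smallest adjusted p 0.137), with 460 at an unadjusted p under 0.05, 231 positive and 229 negative, or 845 with a replicate block. Adjusted over the list alone, 1 gene passed, the histone gene H4c1 of the core histones (-0.86, SE 0.19, adjusted p = 0.0243 over 8 members). Each of the 29 lists was adjusted on its own, so a single call among them can arise by chance. No list passed camera. The smallest adjusted p was 0.485, for oxidative phosphorylation (mean 0.09, 36 of 52 positive), and the pluripotency list had a mean of -0.24 with 14 of 19 negative (adjusted p = 0.597). The endoderm list (0.16, adjusted p = 0.872) and the actin list (-0.06, adjusted p = 0.935) did not pass either. Without the dye term, or with nocodazole replicate 3 given the opposite dye, 1 list passed, oxidative phosphorylation at 0.13. Without nocodazole replicate 1 there were 0 features and 0 lists, with 462 features at an unadjusted p under 0.05, and with the Cy3 arrays turned 0 features, with 676.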

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

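The tests on nocodazole replicate 1 were chosen after the result was seen, as was the choice of the genes it is shown on. A value is listed here where 1 array of a group of 4 lay apart from the other three by Dixon's ratio, and 20 of 138 groups did, where chance gives about 1 in 20 groups, or about 6.9. Of these, 13 concern nocodazole replicate 1. Most rest on genes chosen without that array, so they are not independent of each other or of that choice.

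On nocodazole replicate 1, 11 negative genes and 1 positive gene stood apart from the other three nocodazole arrays: Sparc at 1.24, Serpinh1 at 1.26, Id1 at 1.32, Prph at 1.54, Dab2 at 1.28, Krt8 at 1.41, Gpc4 at 0.82, Slc13a5 at 0.81, Ctsh at 0.69, Spink1 at 1.15, Ctsl at 0.69 and Sav1 at -0.25. The trophectoderm and placenta list stood apart there too, at 0.31 against -0.28 to -0.22.

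Spot noise is argued against: of the 50 leading features of the other 7 arrays, 2 kept their sign on this array, where noise gives about 25. This restates the observation that put the array in doubt. Each other array, left out the same way, kept 23 to 34, and 36 to 47 with nocodazole replicate 1 removed as well, so a first condition that all keep at least 25 failed. A reversal of the line difference shared by the nocodazole arrays is argued against: of the 50 leading features of the untreated arrays 37 kept their sign in the mean of nocodazole replicates 2 to 4 (95% bootstrap interval over features 31 to 43), and 41, 40 and 36 on the single arrays, where it needs under 25. A first bound of 40 for the mean was missed and replaced by this interval, features are not independent, and a response to the drug on replicate 1 alone was not tested. A candidate explanation is that HM-1 and R1 were exchanged between the channels of this array, which would reverse the line difference and leave the dye effect in place. The correlation over features with the dye-following component of the other arrays was 0.193 (95% bootstrap interval 0.169 to 0.217), above 0 as an exchange needs and against a change of sign of the whole column, though a correctly labelled array would give this too. With the array turned and given the opposite dye, limma called 48 features over both conditions and 8 with nocodazole, but the array was doubted on the same values, so these counts are no evidence for an exchange.

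Other values that stood apart are given without an explanation. Untreated replicate 4 held 17928 values against 18142 to 18144. The log2 ratios of nocodazole replicate 3 had a standard deviation of 1.28 against 0.78 to 0.84. Prph was at -1.36 on untreated replicate 4 against -0.86 to -0.75. Nme2 was at 2.50 on nocodazole replicate 4 against -0.66 to -0.37. The list of G1/S and DNA replication genes was at 0.0804 on untreated replicate 2 against -0.06 to -0.05, the pluripotency list at 0.15 on nocodazole replicate 2 against -0.08 to -0.05, and the tubulins at 0.28 on untreated replicate 3 against 0.00 to 0.02.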

How the results depend on the processing

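Alternatives chosen after seeing the data were coded values kept, the Cy3 arrays turned, dim values left out and nocodazole replicate 1 turned. The counts of features stayed at 0 in limma for the 4 comparisons when each array was left out in turn (0 to 0) and under the other alternatives, of which each group alone was run only untreated and with nocodazole, with 3 exceptions, and where these and later values changed, the cause was not tested. On features measured on all 8 arrays, 1 passed with nocodazole, a probe with no listed gene (1.34, adjusted p = 0.0317 against 0.0638 over all features). With nocodazole replicate 1 turned, 8 passed with nocodazole and 48 over both conditions. A replicate block gave 0 calls in all 4 comparisons, with 845 features at an unadjusted p under 0.05 for the change against 460, and took the lists from 5 to 4 untreated and from 2 to 1 with nocodazole. Deviations of arrays with one replicate number correlated at 0.14, 0.04, -0.05 and 0.13, and at most at 0.044, 0.037, 0.13 and -0.0011 with another number. Replicate 3, which did not correlate best with its own number, is the only number whose arrays carry opposite dye labels. Number and dye label are thus mixed, so this check can neither show nor exclude pairs.

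Untreated, 5 lists passed as reported, 3 with nocodazole replicate 3 turned, 2 with the Cy3 arrays turned, 8 with nocodazole replicate 1 turned, 0 with an estimated correlation and 1 to 7 when an array was left out. Germline genes methylated in somatic cells did not pass untreated as reported, but did in some alternatives. They were at 0.13 with quantile normalization (camera adjusted p = 0.0203) and at 0.14 with dim values left out (adjusted p = 0.0216). With dim values left out they also passed with nocodazole, at 0.14 (adjusted p = 0.0132). Feeder fibroblast markers passed untreated with that group alone (-0.14, camera adjusted p = 0.0194) and with dim values left out (-0.19, adjusted p = 0.0256). Without nocodazole replicate 1 they passed untreated (adjusted p = 0.00575), as did trophectoderm (-0.25, adjusted p = 0.0303), and both passed with that array turned. The proteasome list passed untreated without untreated replicate 1 or 3. With nocodazole, 2 passed as reported, 1 with no centring, with scaling, with quantile normalization or with coded values kept, 0 with nocodazole replicate 3 turned or an estimated correlation, 6 with nocodazole replicate 1 turned and 0 to 3 when an array was left out. For the change, 0 passed as reported and 1 with no dye term or with nocodazole replicate 3 given the opposite dye. Of the other results, 850 values kept their side of the threshold and direction, 16 came past it, 37 lost it and 31 changed direction. The single genes counted here had no call as reported that could be lost. All 16 came with nocodazole replicate 1 turned, for genes chosen without that array, so they are no independent support. The 31 came with the Cy3 arrays turned, apart from the fibroblast list with nocodazole replicate 3 turned.

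With the Cy3 arrays turned, the untreated lists were at -0.0681 for endoderm (adjusted p = 0.938), 0.0398 for actin, 0.0444 for cholesterol, -0.0763 for pluripotency and 0.11 for oxidative phosphorylation, and the lists with nocodazole at -0.0224 for actin (adjusted p = 0.992) and 0.000992 for fibroblast markers. The fibroblast list was at 0.0332 with nocodazole replicate 3 turned. With the Cy3 arrays turned the genes over both conditions were at 0.24 for Sparc, 0.41 for Serpinh1, 0.19 for Id1, 0.32 for Prph, 0.29 for Dab2, 0.41 for Krt8, 0.21 for Cryab, 0.17 for Gpc4, 0.15 for Slc13a5, 0.0786 for Ctsh, 0.37 for Spink1, 0.23 for Anxa2, 0.34 for Ctsl, 0.24 for Pth1r, 0.0706 for Thbs1, -0.55 for Ercc6, -0.69 for Dock1, -0.36 for Csnk1e, -0.23 for Sav1, -0.36 for Pecam1, -0.61 for Adamts17 and -0.0233 for Pkd2l1. The changes with nocodazole were then 0.0373 for Il24, -0.0508 for Nme2 and -0.30 for Pla2g12a. Signal over background is unknown, and dim spots limit the ratios. Other filters on missing values were not run for the lists, whose test already used features measured on all arrays.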

Other observations

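The tests on the dye label and on the endoderm, fibroblast and actin genes were chosen after the results were seen, and the markers of fibroblast matrix and of parietal and visceral endoderm were listed then too. The counts of other splits of the arrays were set up before they were run, the one without nocodazole replicate 1 after that array was doubted.

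Without nocodazole replicate 1, single members passed in limma adjusted over the list alone, at most 2 in any other list and more in 3 lists. These were 8 of 22 endoderm genes in untreated cells and 7 with nocodazole, 7 and 6 of 30 fibroblast markers, and 4 and 5 of 41 actin genes. On nocodazole replicate 1 the means of these lists were 0.35, 0.18 and 0.14, against negative means on the other arrays. That array was doubted for such opposite signs, and leaving it out narrows the spread of the genes that have them. Counts and p-values without it are therefore no independent support for these lists. The endoderm list had a camera adjusted p of 4.79e-07 untreated (adjusted p = 0.0989 with an estimated correlation) and a fry adjusted p of 0.00459. Among the members below 0 on all 7 arrays were the apolipoprotein gene Apoe (-0.40 ± 0.14 untreated), the forkhead factor Foxq1 (-0.39 ± 0.19), the galectin Lgals1 (-0.38 ± 0.10), the protease inhibitor Timp2 (-0.54 ± 0.19) and the actin-binding peptide Tmsb4x (-0.42 ± 0.12; SD, n = 4 each). Of these, Foxq1 was negative on nocodazole replicate 1 as well (-0.20). In the fit of all 8 arrays Sod2, the mitochondrial superoxide dismutase, passed over both conditions adjusted over its list of 25 alone (-0.64, SE 0.11, adjusted p = 0.025). It was the only such call over the 29 lists there, which can arise by chance.

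By Pearson's r the arrays grouped by dye label. Dye bias left in ratios that had been turned to one direction is consistent with the code for a denominator of 0, whose sign followed the label on 8 of 8 arrays. A line difference in ratios that were not turned is argued against, since the code was positive on 5 of 8 arrays and negative on the others, where such ratios need one sign. The code does not show which way the ratios ran before, so a line difference in ratios turned into the direction of the dyes stays open. Over 2205 pairs of probes of one gene, Spearman's rho was 0.05 for the component constant over arrays and 0.01 for the one following the dye, a difference of 0.0388 (95% bootstrap interval -0.02 to 0.10) that includes 0. Either reading leaves 0 features past the threshold.

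The means of the endoderm, fibroblast and actin lists were negative on 7 arrays, with 8 of 22, 9 of 30 and 11 of 39 members below 0 on all 7. Dye bias stays open for the endoderm list: its median without nocodazole replicate 1 was 0.0138 in the dye-following component and -0.44 in the constant one, but if the ratios were turned into the direction of the dyes the constant one holds the dye bias. Feeder fibroblasts, on which such lines are often grown, may contribute and stay open: 15 abundant fibroblast matrix genes had a median of -0.04 (from -0.34 for Col1a1 and -0.24 for Thy1 to 0.30 for Lox, with Fn1 at -0.05), above the endoderm list by 0.396, with an interval from -0.03 to 0.65 that includes 0, and 1 endoderm gene is also a fibroblast marker. Parietal endoderm-like cells, a hypothesis named for Sparc, Serpinh1 and Krt8, stay open too: on 4 parietal and 10 visceral genes outside the 15 chosen negative genes the medians differed by -0.189 (interval -1.08 to 0.49), while a first version with all 10 and 11 genes gave -0.80 (-1.03 to -0.15) but rested on genes already seen to be negative. A difference between HM-1 and R1 themselves, which the design names, remains open and untested against these.

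Other sign patterns or splits of the arrays were counted by features at an unadjusted p under 0.05. For the untreated arrays 2 of 8 sign patterns gave as many as the real 888 (highest other 929), and for nocodazole 8 of 8 gave as many as 405 (highest other 1131), too few patterns for a share under 0.05. For the change, 31 of 35 splits gave as many as 460. The highest other split, 2290, set untreated and nocodazole replicates 1 and 2 against the rest. It follows the dye label on all arrays but nocodazole replicate 3. In a fit with the dye term, such a split compares that array with the other arrays labelled HM-1 in Cy5. The count may therefore rest on that 1 array, the one of widest spread (standard deviation 1.28). Over both conditions 22 of 99 patterns gave as many as 775 (highest other 1450), and without nocodazole replicate 1 it was 6 of 62 for 992 (highest other 2383). Chance is not excluded for these last 3 counts.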
